A study of Mus musculus with 48 samples.

How the data were processed

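RNA from the livers of 48 mice was measured on whole mouse genome arrays with 4 arrays per slide, 1 array per mouse, with the mouse's RNA in Cy5 and a pool of all samples in Cy3, in 1 dye orientation. The groups were wildtype or knockout, female or male, and control diet or beta-carotene (150 mg per kg diet, 1500 IU vitamin A per kg in both diets), with 6 mice each, taken from the labels. Mice shared cages with siblings, but the labels do not give the cage, so that siblings could not be modelled. Genotype was also a difference of strain background.

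The deposited scanner files hold signals in the unit intensity: spot and local background brightness, and processed signals after the authors' background subtraction, detrending and dye normalization. The deposited log ratio column is log10 of processed Cy5 over processed Cy3 for most spots. The deposited value table is in log2 and lists 24746 features with a median of 9.32 in each sample. How its channels were combined is not stated; its values followed the Cy5 median signal less the pool's deviation from its mean (largest SD of the difference 0.0203). Per the file headers the signals came from Feature Extraction 9.5.1.1, whereas the submitters' processing notes list 9.5.3.1. The deposited flag columns, other values of 0 or 1, gave the spots well above background.

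The mean signals were background-corrected by normexp (offset 50) with each spot's local background and normalized within arrays by loess, in limma 3.58.1 with statmod 1.5.0 under R 4.3.3. Of 43379 spots per array that were not controls, non-uniform or outlying ones were left out (0.33%). A probe was kept when it was well above background on at least 4 of 6 arrays of at least 1 group, which 25427 probes were, and 25426 had enough values to be tested. Of 25903 probes with a RefSeq accession 24375 matched the reference annotation, and 4783 were renamed by it. For each gene 1 probe was taken, which gave 17533 genes, 13605 of them with a symbol. Positions are on mm8, the build in the annotation of the arrays.

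A linear model with 8 group means was fitted to all 48 arrays (40 residual degrees of freedom) with moderated t tests, and p-values were adjusted by Benjamini and Hochberg within each of 12 comparisons at 0.05. The comparisons were the diet in each sex and genotype, genotype in each sex and sex in wildtype mice on the control diet, and 5 interactions. The fit was unpaired. In all, 17 gene lists and 11 cell type marker lists were fixed before the data were examined and tested by camera with a preset correlation of 0.01 and, beside it, an estimated correlation, adjusted over 28 lists. Genes within 20 Mb of Bco1 were compared with the others by Fisher's exact test.

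Named genes followed a rule fixed before the data were examined. It took Bco1 in each comparison, and the 8 highest and 8 lowest log2 fold changes among genes with a symbol past the threshold. Where none passed, it took the 3 smallest p in each direction. It also took the members of lists with the smallest p, of which some are left out for length. A few genes that the rule gives are not reported here. For the interactions it took 4 in each direction and 2 per list.

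Red spots well above background numbered 22576 to 27940 per array (median 26074.5). On simulated changes added to the comparison of diets in wildtype females, 57 of 67 genes shifted by 0.5 on the log2 scale were called, 66 of 67 at 1 and 66 of 66 at 2, with 5 calls among 17333 unshifted genes. A list of 39 genes shifted by 0.3 passed and 0 of 27 others did. The simulated genes varied independently, so these simulations do not show how the tests behave with correlated genes. When the real arrays of that comparison were split at random, a median of 6 lists was called (up to 15), and up to 106 genes. No arrays were duplicates (largest correlation of log ratios 0.786).

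The alternatives were processed signals, no background subtraction, Aquantile or scale normalization between arrays, no filter or a stricter one (6 of 6 arrays), all probes, slide as a fixed or random block, the replicate number as a block, array weights, the value table, only the groups compared, and each array left out in turn. The median background of each array in normexp, and leaving out the 8 arrays with a normexp background mean under -200, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.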

Results

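Liver expression was measured on 48 two-colour arrays, 1 per mouse. The wildtype mice were B6129SF1 and the knockout mice came from the B6;129S-Bcmo1-/- stock. Bco1, named Bcmo1 in the files, encodes the enzyme that cleaves beta-carotene into retinal. Females and males of each genotype ate a control diet or the same diet with 150 mg beta-carotene per kg for 14 weeks, which gave 8 groups of 6 mice. Between 22576 and 27940 spots per array were well above background in the Cy5 channel that carried the mouse's own RNA. On 8 arrays, picked after the data were seen by a normexp background mean under -200, the log ratios were narrower on average than on the other 40 (mean SD 0.213 against 0.306), with overlapping ranges (0.181 to 0.276 and 0.228 to 0.342).

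The Bco1 probe, at chromosome 8:120019073 to 120019132 of mm8, separated the genotypes in both sexes. On the control diet its log2 ratio to the pool was -0.67 ± 0.48 in knockout females and 0.72 ± 0.12 in wildtype females (mean ± SD, n = 6 each), a difference of -1.39 (SE 0.17, limma adjusted p = 7.83e-08). In males the values were -0.94 ± 0.24 and 0.36 ± 0.22, a difference of -1.29 (SE 0.17, adjusted p = 2.94e-07). The size depended on the processing (-3.19 to -1.07 in females and -2.84 to -0.98 in males over the alternative fits, the larger with processed signals). The highest of the 24 knockout arrays, at -0.04, lay below the lowest of the 24 wildtype arrays, at 0.01 (-0.94 and 0.30 with processed signals). The probe was still above background on 5 or 6 of the 6 arrays of every knockout group, and the labels do not say which exons were deleted.

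**Figure D1:**
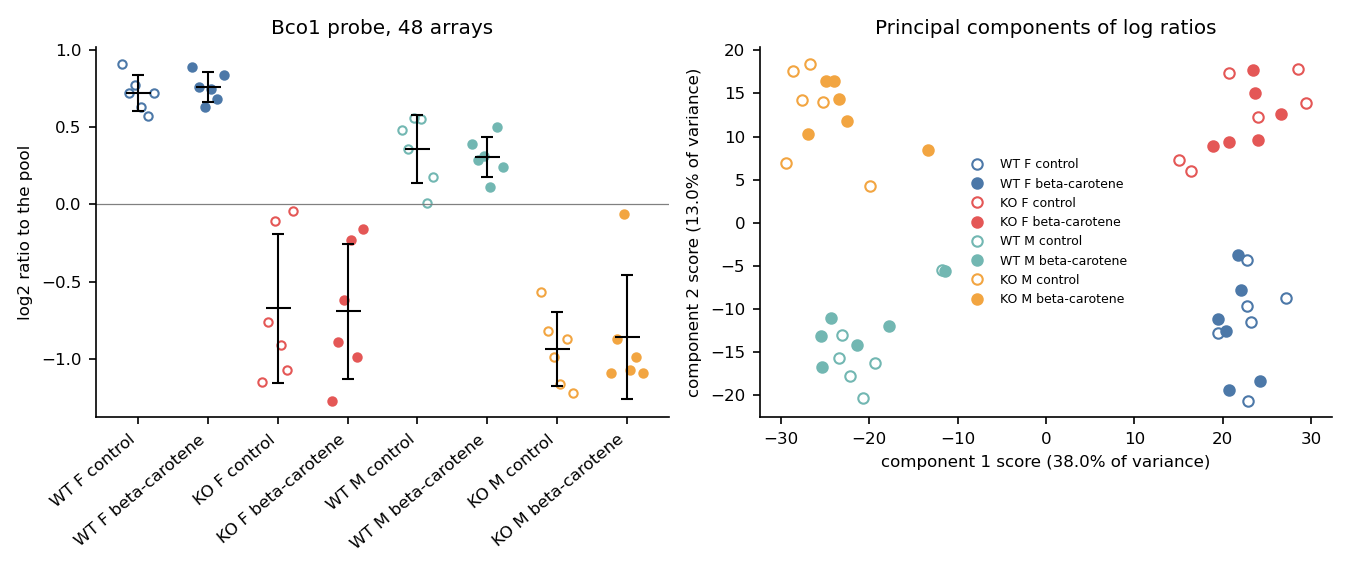
Left, log2 ratio of the Bco1 probe to the common pool on each array, with group means and SD as bars (n = 6 per group); open circles are control diet and filled circles beta-carotene. Right, scores of the 48 arrays on the first principal components of the log ratios, where component 1 (38.0% of variance) parted the sexes and component 2 (13.0%) parted the genotypes.

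Whether beta-carotene changes the wildtype liver, where it can be cleaved, was asked in each sex. In females Slc38a5, an amino acid transporter, fell from 1.23 ± 0.38 to 0.29 ± 0.22, a log2 change of -0.94 (SE 0.15, limma adjusted p = 0.0032, n = 6 per group). It was the 1 gene of 17533 past the threshold, and lost its call with processed signals (adjusted p = 0.724) and with only the groups compared. At unadjusted p under 0.05 there were 795 genes (4.53%), below the share of 0.05 that no effect would give. In males none passed by limma, 320 (1.825%, also below that share) had unadjusted p under 0.05, and the other fits called 0 or 1 gene. Among genes with a symbol, the 3 with the smallest p in the upward direction in males were Raet1a (0.71, SE 0.15, adjusted p = 0.478), Cyp26a1, which degrades retinoic acid (1.48, SE 0.40, adjusted p = 1), and H2al1n (0.34, SE 0.10). Each was higher in 6 of 6 slides that held both diets. In the downward direction they were Rrm2b (-0.18), Cyp3a44 (-0.63) and Cyp3a11 (-0.54), lower in 5 of 6 slides, none of them past the threshold. Bco1 differed between the diets by 0.04 in females and -0.05 in males, less than its spread between mice.

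The cholesterol synthesis list moved in opposite directions in the sexes of wildtype mice. Of 28 measured genes, 26 were lower in females on beta-carotene (median -0.33, camera adjusted p = 1.92e-06) and 27 were higher in males (median 0.34, adjusted p = 1.52e-14). Hmgcs1 (-0.54, SE 0.30) and Insig1 (-0.62, SE 0.37) had the smallest p of the list in females. Idi1 (0.85, SE 0.36) and Sqle (1.08, SE 0.51) were 2 of the 3 with the smallest p in males, and 0 genes of the list passed, over all genes or over the list alone. With an estimated correlation between the genes the adjusted p was 0.678 and 0.481. Without the 8 arrays the male call was lost (0.382), and with scale between arrays the female call was. Fatty acid and triglyceride synthesis followed the same directions (adjusted p = 0.00311 in females and 0.00662 in males). Wildtype females also had lower cell cycle (0.00289) and NRF2 (0.0459) lists and higher male-biased (0.00289) and interferon (0.0326) lists. Wildtype males had a higher heat shock list (0.000479) and a lower xenobiotic list (0.00346). The retinoic acid target list passed upward (0.0397) on its mean of 0.11, although 13 of its 27 genes rose and 14 fell. None of these 11 calls held with an estimated correlation, and 0 list members passed over all genes. In females 0 of the 6 calls held with scale, where the male-biased list turned downward (0.365), and the male-biased and NRF2 lists lost theirs with the median background (0.0816 each). In males the fatty acid synthesis (0.423, turned downward), xenobiotic (0.237) and retinoic acid target (0.0867) lists lost theirs without the 8 arrays, and the last also with slide as a fixed block (0.0605).

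In knockout mice, which lack the enzyme, the diet comparison asked what intact beta-carotene does. Knockout females on beta-carotene had lower Gdpd3, a glycerophosphodiester phosphodiesterase, at -1.39 ± 1.20 against 0.45 ± 0.62 (log2 change -1.84, SE 0.30, adjusted p = 0.00484, n = 6 per group). It lost its call in 6 alternative fits, and with the median background of each array in place of the local background its adjusted p was 0.0729. Knockout female control replicate 3, on 1 of the 8 arrays with a low normexp background, then moved from -0.66 to -2.78, to the level of 3 of the 6 arrays on beta-carotene (-2.87 to -2.74). No other gene passed, and 677 (3.86%) had unadjusted p under 0.05, below the share of 0.05 that no effect would give. With the median background Trim12a stood at its higher level in 2 of 6 knockout female controls and in all 6 on beta-carotene. Gdpd3 followed Trim12a inversely among knockout arrays, so for Gdpd3 the diet cannot be told apart from that level.

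Interferon response and antigen presentation genes were lower in knockout females on beta-carotene. Of 50 measured genes 40 fell, with a median of -0.17 (camera adjusted p = 1.75e-10, 0.180 with an estimated correlation). Isg15 (-0.52, SE 0.17), Iigp1 (-0.53, SE 0.17) and Ifi35 (-0.37, SE 0.08, adjusted p = 0.133) had the smallest p of the list, each lower in 5 of 5 slides that held both diets. One gene passed when adjusted over the list alone and 0 over all genes. With the median background 11 genes passed over all genes, Gdpd3 not among them; they included Ifi35 (adjusted p = 0.0181) and, chosen after their values were seen, Oas1c (0.0157) and Dhx58 (0.027). The fatty acid oxidation list was lower (37 of 45 genes, median -0.18, adjusted p = 6.95e-07) and the extracellular matrix list higher (32 of 35, median 0.12, 1.08e-07). The erythroid (1.82e-06), acute phase (4.45e-05), male-biased (3.99e-04), bile acid (0.00141) and cell cycle (0.00333) lists were lower. Stellate cell (7.02e-05), fatty acid synthesis (3.99e-04), adipocyte (0.00971), NRF2 (0.0265) and cholangiocyte (0.0339) lists were higher. Over all genes 0 members of the 13 lists passed. None of the 13 held with an estimated correlation, and the adjusted p then ranged from 0.0828 upwards. Without the 8 arrays the fatty acid synthesis (0.296), bile acid (0.494), male-biased (0.411), cholangiocyte (0.0630; 0.0559 with slide as a fixed block) and NRF2 (0.981, turned downward) lists lost their call, and with the median background the male-biased list did (0.190). The cell cycle list turned upward in 6 alternative fits, past the threshold with scale (4.43e-05), and the male-biased list turned upward with scale (0.193).

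**Figure D2:**
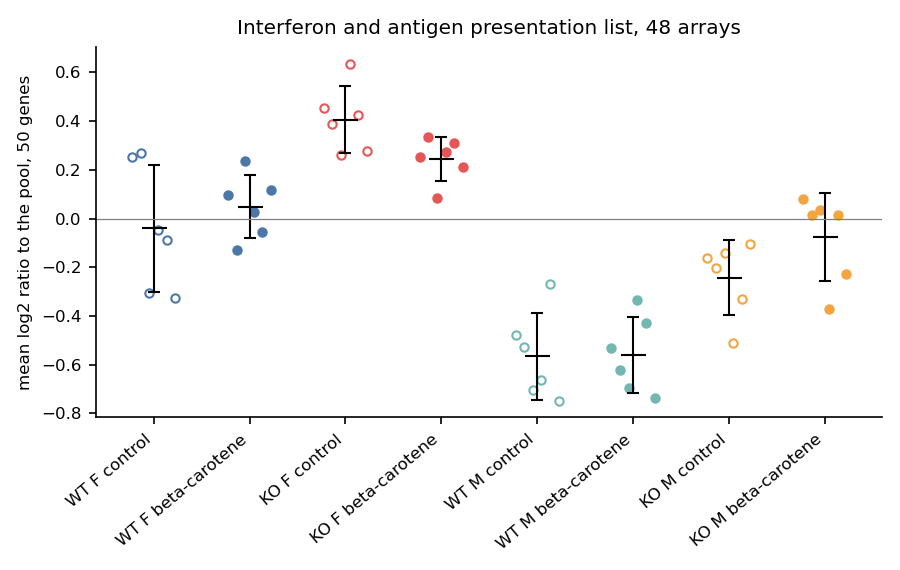
Mean log2 ratio to the pool of the 50 measured interferon and antigen presentation genes on each array, with group means and SD as bars (n = 6 per group). Knockout females lay highest, at 0.41 ± 0.14 on the control diet and 0.24 ± 0.09 on beta-carotene, and wildtype males lowest, at -0.56 on both diets.

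Knockout males on beta-carotene had 3 genes past the threshold. Raet1a, a ligand of the NKG2D receptor, rose from -1.01 ± 0.29 to -0.11 ± 0.27 (0.90, SE 0.15, adjusted p = 0.00453), and was higher in 6 of 6 slides. Fzd6, a Wnt receptor, fell from 0.46 ± 0.42 to -0.55 ± 0.30 (-1.0, SE 0.17, adjusted p = 0.00453). Slc22a7, an organic anion transporter, fell from 1.00 ± 0.49 to -0.10 ± 0.22 (-1.09, SE 0.21, adjusted p = 0.0285). Both were lower in 6 of 6 slides. All 3 lost their call with only the groups compared, Raet1a and Slc22a7 with scale between arrays (adjusted p = 0.961 each), and Slc22a7 in the value table, without the 8 arrays (0.0562) and in 7 of 12 fits that each left out 1 array. The heat shock list was lower (35 of 39 genes, median -0.17, camera adjusted p = 2.22e-09), with Chac1 at -0.98 (SE 0.41). The fatty acid oxidation (43 of 45 genes, median 0.16, 3.59e-08), cell cycle (45 of 46, 0.19, 4.50e-08) and interferon lists (44 of 50, 0.12, 6.57e-08) were higher, with Acot3 at 0.94 (SE 0.37) and Usp18 at 0.54 (SE 0.24). The female-biased (6.12e-04) and T or NK cell (0.00423) lists were higher and the extracellular matrix (0.00113), stellate cell (0.00155) and male-biased (0.0276) lists lower, and none of the 9 held with an estimated correlation (0.497 or more). In the 9 lists 0 genes passed, over all genes or over the list alone. With the median background the female-biased (0.0988), extracellular matrix (0.108) and male-biased (0.0589) lists lost their call, the first also without the 8 arrays (0.274). With scale 3 of the 9 held, while the fatty acid oxidation (7.45e-06) and male-biased (0.00103) lists passed in the other direction, and so did the female-biased list (1.26e-05).

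The genotype comparison on the control diet gave many more differences, and genotype was also a difference of strain background. In females 772 genes were higher and 588 lower in knockouts (n = 6 per group). Slco1a1, an organic anion carrier that is male-biased in the liver, rose from -4.45 ± 1.03 to -0.54 ± 0.72 (log2 change 3.91, SE 0.31, adjusted p = 6.01e-13). Sult3a1 (2.83), Marco (2.51), Ifi202b (1.64), Rab6b (1.51), Sult5a1 (1.40), Mt1 (1.33) and Rusc2 (1.33) completed the 8 largest increases among genes with a symbol. Marco and Mt1, with SDs of 0.57 to 1.81, kept their call in 9 and 5 of 12 fits that each left out 1 array, with the highest adjusted p without wildtype female control replicates 6 and 4 (0.0555 and 0.0924). The 8 largest decreases among them were in Htatip2 (-3.31), Ctse (-3.14), Abhd1 (-2.77), Cyp2c38 (-2.42), Depdc6 (-2.22, SE 0.08, adjusted p = 4.51e-24), Ren2 (-1.88), Ccl27a (-1.83) and Cyp2a4 (-1.65).

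Of 34 measured genes of carotenoid and retinoid metabolism 3 were higher and 3 lower in knockout females, and the list did not pass (camera adjusted p = 0.525). Bco2, which cleaves carotenoids at another bond, was higher in knockouts (0.57, SE 0.09, adjusted p = 7.22e-06), as was Lrat, which esterifies retinol (0.87, SE 0.14, 2.60e-05), while the retinol receptor Stra6 was lower (-0.67, SE 0.10, 1.46e-05). Nr5a2 (-1.45) and Cps1 (-1.40) fell, and Apcs (0.99) and Hspb1 (1.02) rose. Interferon and antigen presentation genes were higher: 27 of 50 passed over all genes, 33 adjusted over the list alone, and the median was 0.45 (camera adjusted p = 5.24e-18). Psmb9 (0.73), Psmb8 (0.63) and Ifi35 (0.48) were among them. Kupffer cell or macrophage markers rose as well, with 11 of 18 passing (14 adjusted over the list alone; median 0.47, adjusted p = 3.12e-09), including Cd5l (0.79) and C1qa (0.64). The male-biased (1.28e-04) and cell cycle (0.00215) lists were higher, and with an estimated correlation the adjusted p of these 4 lists was 0.271, 0.416, 0.416 and 0.738. The male-biased and cell cycle lists lost their call with the median background (0.215 and 0.195), and the former without the 8 arrays (0.102), while with scale it passed downward (5.04e-04).

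In males 1019 genes were higher and 967 lower in knockouts (n = 6 per group). Among genes with a symbol Moxd1 rose most (3.71, SE 0.60, adjusted p = 1.48e-05), followed by Selenbp2 (2.20), Asns (2.15), Marco (2.11), Sqle (2.09), Dct (1.92), Rnase2a (1.75) and Tmc5 (1.72). Myom2, a muscle structural protein, fell most, from 1.74 ± 0.39 to -2.56 ± 0.36 (-4.30, SE 0.36, 3.06e-12). Htatip2 (-3.68), Ctse (-3.35), Abhd1 (-2.94), Ccl27a (-2.57), Rad51b (-2.48), Depdc6 (-2.27) and Cyp2c38 (-2.27) followed. Marco kept its call in 5 of 12 fits that left out 1 array. The 16 genes of these 2 sets changed in the stated direction in 5 of 5 slides that held both genotypes, except Cyp2c38, measured in 4 of them and lower in 4. Lrat (0.96) and Stra6 (-0.60) changed as in females, and so did Nr5a2 (-1.37), Cps1 (-0.92), Apcs (1.06) and Hspb1 (1.11).

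Interferon genes were higher in knockout males as well, with 11 of 50 passing (17 adjusted over the list alone; median 0.30, camera adjusted p = 1.28e-09), among them Ifi47 (0.86), Ifi27 (0.81) and Psmb8 (0.81). Heat shock genes rose (12 of 39, 18 over the list alone, 0.35, 2.16e-08), and Kupffer cell markers did too (11 up and 1 down of 18; 16 up and 1 down adjusted over the list alone; 0.49, 4.32e-08), with Cd5l at 0.77. Male-biased genes rose (13 up and 1 down of 34, median 0.45, 4.32e-08) and female-biased genes fell (1 up and 10 down of 33, -0.49, 1.14e-04), although the male-biased Cyp4a12a fell by 1.04. Cholesterol synthesis genes rose (4 of 28, 9.88e-04), with Hmgcs1 at 1.25, while the fatty acid regulator Srebf1 fell (-1.11, SE 0.32, 0.0159). Stellate cell (3.88e-05), extracellular matrix (5.40e-05), endothelial (0.00356), cholangiocyte (0.0324) and acute phase (0.0367) lists were higher. Fatty acid oxidation (8.09e-04) and xenobiotic (0.0260) lists were lower. None of the 13 held with an estimated correlation (0.223 or more), the xenobiotic list lost its call without the 8 arrays (0.0678), and the acute phase list with slide as a fixed block (0.0613). With scale 7 of the 13 held, not the male-biased list, and the fatty acid oxidation (0.992), xenobiotic (0.992) and female-biased (0.711) lists turned.

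**Figure D3:**
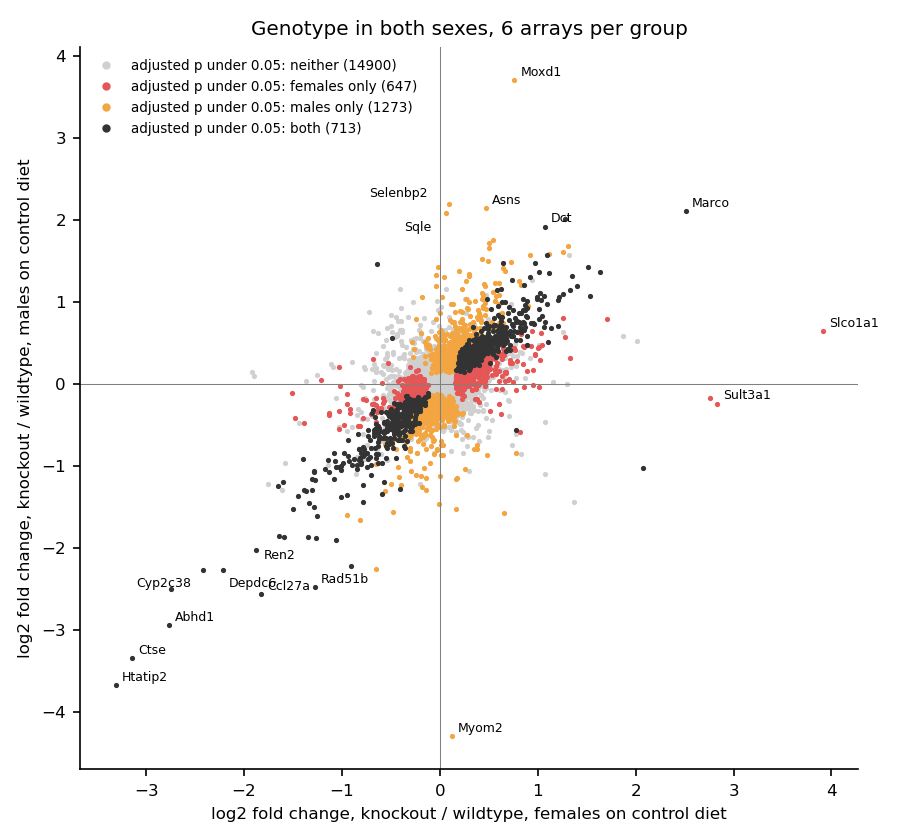
Log2 fold change of knockout over wildtype on the control diet for 17533 genes, females on the x axis and males on the y axis, coloured by adjusted p under 0.05 in females, males, both or neither; some of the genes with the largest changes are named. The 713 genes past the threshold in both sexes had the same sign in both, except for 4.

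The calls of the sexes overlapped, and no array was shared between them. Of the genes past the threshold, 381 were higher in knockouts of both sexes where independence gave 44.9, 328 were lower in both (32.4), and 4 had opposite signs. Within 20 Mb of Bco1, 23 of 275 genes passed in females and 35 of 275 in males (8.36% and 12.7%), against 1324 and 1934 of 17130 elsewhere (7.73% and 11.3%; Fisher's exact test, two-sided p = 0.650 and 0.443). Among genes with a second tested probe, that probe was called in the same direction for 190 of 506 in females and 271 of 730 in males, and in the opposite direction for 15 and 21.

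Wildtype females and males on the control diet differed in 2711 genes, 1444 of them higher in females (n = 6 per group). Xist (7.93), Sult2a2 (7.23), Sult3a1 (6.39), Hao2 (5.16), Slc22a26 (4.90), Cyp2b9 (4.70) and Cyp2b13 (4.03) were among the genes with a symbol that had the largest changes toward females. Cyp4a12a (-5.40, SE 0.15, adjusted p = 2.81e-29), Hsd3b4 (-5.05), Ddx3y (-4.84), Slco1a1 (-4.82), Nat8 (-4.44) and Mup1 (-4.33) were among the 8 with the largest changes toward males. Eif2s3y and Nat8f5 were not above background in females, so that they were at least 62.6-fold and 13.4-fold lower there. Female-biased (29 up and 1 down of 33, median 1.93, camera adjusted p = 3.55e-50) and male-biased lists (31 down of 34, -1.93, 1.97e-63) separated, also with an estimated correlation (9.20e-07 and 1.42e-08). Acute phase (19 up and 2 down of 49, 0.29) and endothelial genes (10 of 19, 0.27) were higher in females and held as well (0.0202 and 0.0131). Bco1 was 0.36 higher in females (SE 0.17, adjusted p = 0.150). Only 1 slide held both sexes of wildtype mice.

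Interferon genes were higher in wildtype females (29 of 50, 39 over the list alone, median 0.43, 1.80e-18), and Kupffer cell markers likewise (13 of 18, 16 over the list alone, 0.55, 2.20e-10). Cholesterol synthesis (12 of 28, 0.61, 1.98e-07), T or NK cell (8 of 19, 2.24e-05), xenobiotic (28 up and 19 down of 71, 3.44e-04), cell cycle (7.58e-04), extracellular matrix (8.52e-04), stellate cell (0.00108) and fatty acid oxidation (0.00355) lists were higher, and bile acid genes lower (0.0493; 0.0902 with the median background). With slide as a fixed block the bile acid (0.147) and cell cycle lists lost their call, and with scale the fatty acid oxidation, bile acid and xenobiotic lists did. With an estimated correlation these lists gave 0.0543 or more.

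Whether the diet acted differently by genotype or by sex was tested with interaction terms. No gene passed for diet by genotype in females or males by limma, with 1155 (6.59%) and 338 (1.93%) at unadjusted p under 0.05. In females the other fits gave between 0 and 25 genes, and in males they all gave 0. Gsta2 (1.55, SE 0.37), Ociad2 (0.85), Olfr845 (0.32), Parp9 (-0.53), Ifi35 (-0.48) and Impa1 (-0.30) were the 3 with the smallest p in each direction in females, all at adjusted p = 0.211. Gpat3 (1.72), Cyp3a44 (1.08), Cyp3a11 (0.89), Slc22a7 (-1.10), Fzd6 (-1.06) and Gpr162 (-0.39) were those in males, all at adjusted p = 1. The response of the interferon list to beta-carotene was lower in knockout than in wildtype females (39 of 50 genes, median -0.30, camera adjusted p = 1.19e-07, 0.296 with an estimated correlation). In males the heat shock response was lower in knockouts (35 of 39, -0.26, 3.09e-13, 0.331).

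In knockouts Gdpd3 differed in its response between the sexes (-2.44, SE 0.43, adjusted p = 0.0171), the 1 gene past the threshold. This SE too pools the variance of all 8 groups, including the wildtype groups with little spread. The call of Gdpd3 was lost with processed signals, no background subtraction, scale between arrays, the value table and the median background (0.0996). With the replicate block and with only the groups compared the call was lost too. It was also lost without knockout female control replicate 2 (0.0637), knockout male control replicate 3 or knockout male beta-carotene replicate 2. With the median background Gdpd3 followed Trim12a inversely among knockout arrays. On beta-carotene Trim12a was high in knockout females and low in knockout males, and it was mixed in both control groups. The difference in response of Gdpd3 cannot be told apart from that level. Interferon genes responded lower in knockout females than in knockout males (43 of 50, median -0.29, 5.23e-16, 0.10 with an estimated correlation; 12 genes adjusted over the list alone, 0 over all), and fatty acid oxidation genes did too (44 of 45, -0.41, 1.74e-13, 0.351). In wildtype mice no gene passed for diet by sex by limma, with 580 (3.31%) at unadjusted p under 0.05. The other fits called 0 or 1. Slc38a5 had the smallest p (-1.14, SE 0.21, adjusted p = 0.059), ahead of Atp5mpl (-0.21), Slc24a2 (0.31), Cyp3a44 (0.96) and Foxo3a (0.34), each at adjusted p = 1. All 28 cholesterol genes responded lower in wildtype females than in males (median -0.71, 4.37e-17, 0.285).

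The genotype difference itself depended on sex in 31 genes, of which 21 were shifted upward in females relative to males. The count was 16 to 49 with 1 array left out (without knockout female control replicate 6 and wildtype male control replicate 3) and 8 with scale to 142 with array weights. The weights were highest on knockout female control replicates 3 and 6, which had narrow log ratios. More genes were shifted downward than upward with scale (7 and 1), without the 8 arrays (39 and 26) and in the value table (50 and 28). Without knockout male control replicate 3 alone, 9 were shifted downward and 8 upward. Myom2 (4.42, SE 0.51, adjusted p = 3.68e-07) was lower in knockout males only, since knockout and wildtype females lay at -1.95 and -2.07. Slco1a1 (3.27), Vldlr (1.61) and Cyp2b9 (1.34) were also shifted upward. Selenbp2 (-2.11), Camk2b (-2.10), Selenbp1 (-1.44) and Slc38a5 (-1.41) were shifted downward. The bile acid list was shifted upward in females (27 of 35, 4.29e-05) and held with an estimated correlation (0.0483), but not with scale. Female-biased genes were too (25 of 33, median 0.29, 1.26e-07, 0.161), and heat shock genes downward (34 of 39, -0.30, 9.83e-09, 0.268). The interaction for Bco1 was between -0.10 and 0.13 in all 5 tests.

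**Figure D4:**
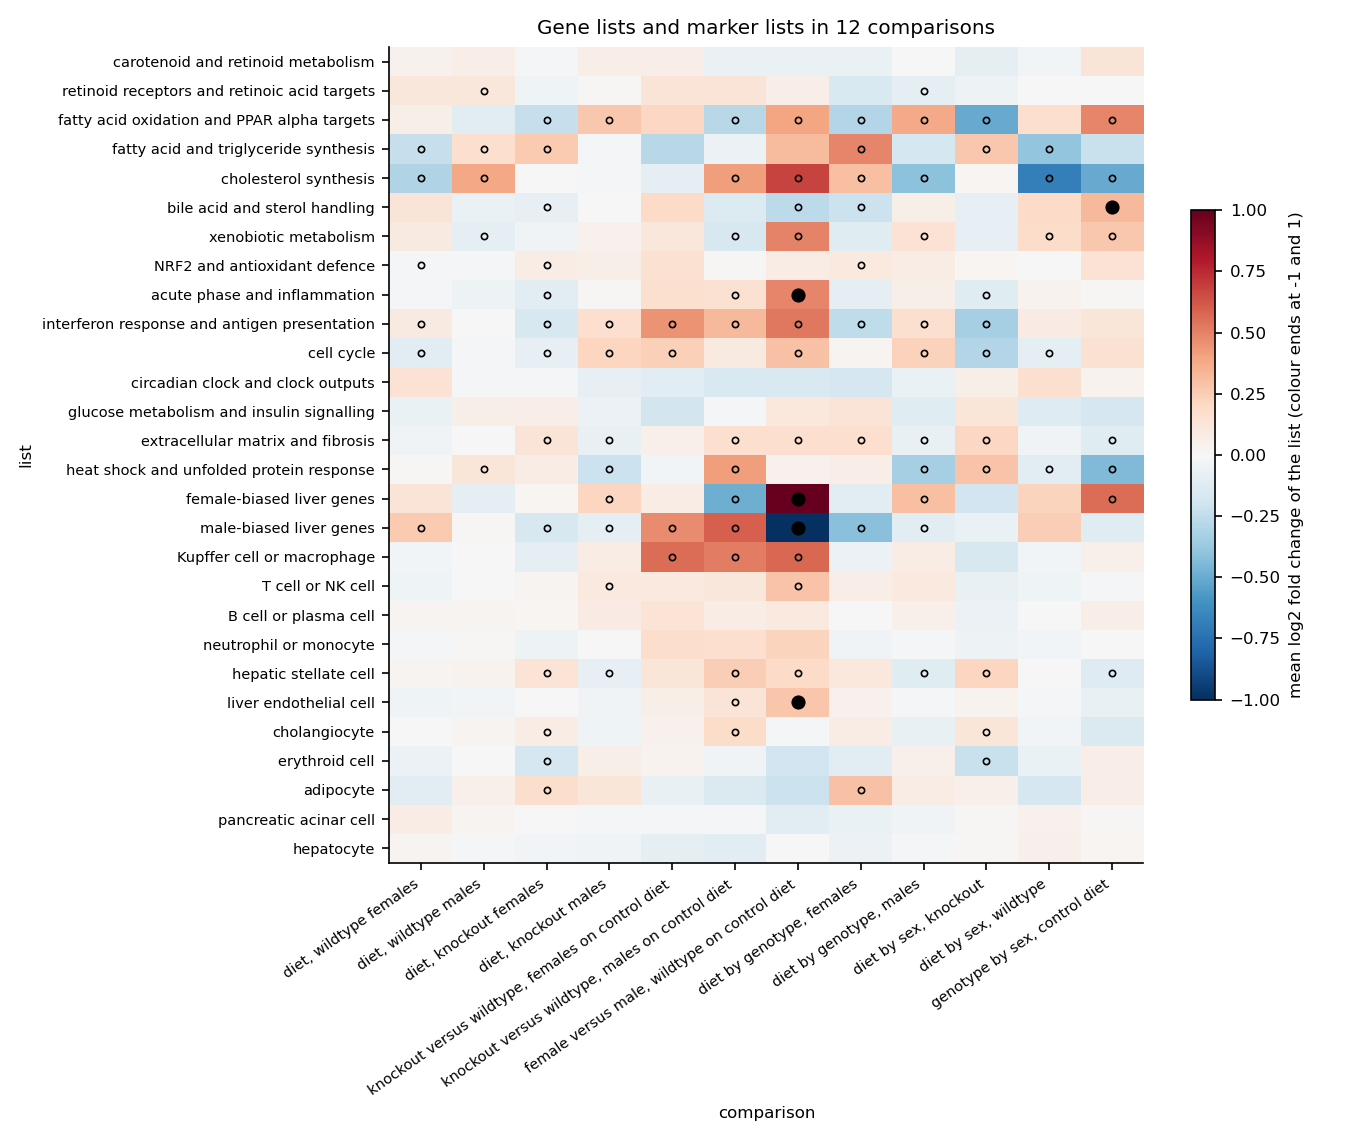
Mean log2 fold change of 28 gene and marker lists (rows) in the 12 comparisons (columns), with the colour scale ending at -1 and 1. Circles mark the 107 of 336 pairs with camera adjusted p under 0.05, large and filled for the 5 that also passed with an estimated correlation and open for the rest.

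Of the 336 pairs of list and comparison, 107 passed. The carotenoid and retinoid metabolism (smallest adjusted p = 0.107), circadian clock (0.298), glucose metabolism (0.0901), hepatocyte (0.0909), pancreatic acinar cell (0.183), B cell (0.157) and neutrophil or monocyte (0.0540) lists passed in none of the 12 comparisons.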

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

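The 2 tests on narrow log ratios, the tests of neighbours beyond 1 Mb, of failed arrays and of beta-carotene for expression at 2 levels, and the test without 8 arrays for the interferon list were chosen after the results were seen. The bounds by which alleles and beta-carotene were judged for expression at 2 levels were also reset then.

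In 289 tests of a value over 6 arrays, an array lay far from the other 5 in 29, where chance gives about 1 in 20, or 14.4. Wildtype male control replicate 5 had a narrow SD of log ratios (0.189) and values less negative than on the other 5 for Sult3a1 (-5.63), Sult2a2 (-5.31), Xist (-3.71), Slc22a26 (-2.02) and Moxd1 (-0.58). Knockout male beta-carotene replicate 3 had a narrow SD (0.22) and Bco1 at -0.06. The pool channel of wildtype male control replicate 2 had 19990 spots well above background, and H2al1n lay at -0.80 there and at 0.53 in wildtype male beta-carotene replicate 2. In knockout male controls Fzd6 (1.30) and Slco1a1 (0.73) stood out in replicate 3, and Cyp4a12a (-0.58) and Acot3 (-1.57) in replicate 1.

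In wildtype female controls Ifi35 (-0.09) stood out in replicate 1, Atp5mpl (0.03) in 2, Sult3a1 (0.21) and Cyp4a12a (-3.56) in 3, Abhd1 (0.55) in 4, and Marco (2.04) and Ociad2 (-0.56) in 5. In knockout female controls Psmb8 (0.16) stood out in replicate 3, Mt1 (-0.24) and Parp9 (0.08) in 4, Sult5a1 (-1.30) and Hspb1 (-0.48) in 5, and Cyp2b9 (1.73) in 6. Gsta2 was at -0.57 in wildtype female beta-carotene replicate 5.

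Effects differed between groups by interaction tests. Genotype by sex gave 31 genes, with Myom2 at 4.42, Slco1a1 at 3.27, Vldlr at 1.61, Cyp2b9 at 1.34, Selenbp2 at -2.11, Camk2b at -2.10, Selenbp1 at -1.44 and Slc38a5 at -1.41. Diet by sex in knockouts gave 1 gene, Gdpd3 (-2.44). Lists passed in diet by genotype (9 in females, 11 in males), diet by sex (10 in knockouts, 5 in wildtype mice) and genotype by sex (8), of which 0, 0, 0, 0 and 1 held with an estimated correlation.

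The log ratios of 8 arrays from 5 groups were narrower on average than those of the other 40 (mean SD 0.213 against 0.306). Knockout female control replicates 3 and 6 were among the 8 and no wildtype female was, so genotype in females held such arrays on the knockout side only. Weaker labelling was argued against by the spots well above background, whose mean on the 8 arrays was 0.269 SD above that of the others. With the median background of each array in normexp the mean SD of the 8 arrays was 0.667 SD above that of the others, so that spots with extreme local background may have pulled the normexp background down. No biological explanation was tested.

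Some genes stood at 2 levels, at least 1.5 apart on the log2 scale with the median background, within a group: 16 in knockout females on beta-carotene and 4 to 15 in the others. A single failed array behind most of these genes was argued against in the 2 knockout groups with at least 5 genes of unequal sides. No array there was on the minority side in more than 63.64% of such genes, under a bound of 75%. Knockout female beta-carotene replicates 2 and 3 each reached that share, with 7 of 11 genes on the minority side. A pair of arrays behind many of these genes was therefore not argued against. In knockout male controls replicates 1 and 4 were on that side in 2 of 2. Mice swapped between diets need not lie on the minority side, so mixed-up arrays could not be tested in this way. Alleles that segregate in the knockout stock cannot be told apart: 12.96% of the closest genes lay within 20 Mb against 1.65% expected by position, but 14.33% did for wildtype mice (Fisher's exact p = 0.715), and beyond 1 Mb 8.148% against 7.667% (p = 0.877), and a p above the threshold does not show equal shares. Beta-carotene cannot be told apart as the reason for the levels of Gdpd3, since the 1 control-diet knockout female at the lower level is a single array.

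The interferon list was lower in knockout females on beta-carotene, and without the 8 arrays with narrow log ratios it still was (camera adjusted p = 6.912e-14). Its direction therefore did not rest on those arrays alone. That p used the preset correlation, under which other splits of the knockout female arrays called a median of 8 lists, so it cannot exclude them as a reason. The T or NK cell markers moved by 0.02 (95% interval -0.12 to 0.17), or 0.19 above the interferon list (0.04 to 0.33). This argued against a fall of these markers as large as that of the list. The list was picked from 28, which may widen the gap, and a smaller fall in T or NK cells cannot be excluded. Fewer Kupffer cells or macrophages cannot be told apart, since their markers moved by -0.09 (0.07 above the list, -0.07 to 0.22). Shared movement between single mice cannot be told apart either: the exact permutation p was 0.02597 over 924 splits that ignored slide (0.00217 with the median background), but the list was picked from 28, and adjusted over them p was 0.576 (0.0606). Within slides the list was lower in 5 of 5 (-0.386 to -0.00261), and an effect of beta-carotene, and siblings sharing cages, which was untested, may each remain.

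Other splits of the same arrays (100 each, the real one included) excluded chance for the number of genes in 4 comparisons. These were genotype in females (1360, highest other 525; 1 split as large), genotype in males (1986, 1220; 1), sex (2711, 1442; 1) and genotype by sex (31, 1; 1). Chance was not excluded for the diet in wildtype females (1, 106; 15), knockout females (1, 270; 19) or knockout males (3, 13; 6), or for diet by sex in knockouts (1, 18; 12). Where 0 genes were called every split was as large (100 of 100), so the splits decide nothing for the diet in wildtype males (highest other 35), diet by genotype in females (185) and males (2) or diet by sex in wildtype mice (3). The splits ignored slide. Splits that called several times the real count, up to 270 genes, point to a structure among the arrays of a group.

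For the number of lists, 4 of the 100 splits were as large for the diet in knockout females (13, highest other 13), a share under 0.05 in 1 of 12 comparisons, which does not exclude chance over the 12. Nor was chance excluded for the diet in wildtype females (6, 15; 57), wildtype males (5, 12; 55) and knockout males (9, 14; 25), genotype in females (4, 14; 89) and males (13, 15; 6) or sex (14, 16; 9). It was not excluded for diet by genotype in females (9, 18; 28) and males (11, 14; 10), diet by sex in knockouts (10, 15; 17) and wildtype mice (5, 16; 68), or genotype by sex (8, 15; 28).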

How the results depend on the processing

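The fits with the median background and without the 8 arrays with a low normexp background were chosen after the data were seen; the other alternatives were planned. The Aquantile step moves no log ratio and so tests nothing. Unless stated, the cause of a change was not tested.

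The number of genes called for the diet in wildtype females (1, Slc38a5) was 2 with processed signals, neither of them Slc38a5, and 2 with no background subtraction, scale between arrays, slide as a random block, the value table, the median background and the 8 arrays left out, 4 with slide as a fixed block, and 0 with only the groups compared. In wildtype males (0) it was 1 with slide as a fixed block. In knockout females (1) it was 8 with processed signals, 9 without background subtraction, 2 with scale, 4 and 3 with slide as a fixed and random block, 18 with array weights, 5 in the value table and 11 with the median background. In knockout males (3) it was 5 with processed signals, all probes and the 8 arrays left out, 1 with scale, 6 with array weights and 0 with only the groups compared.

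Scale between arrays lowered genotype in females from 1360 to 446, genotype in males from 1986 to 456 and sex from 2711 to 497. Array weights gave 2309 for genotype in females, and the median background gave 1885. The highest array weights, 4.177 and 3.605, fell on knockout female control replicates 3 and 6. Both had a low normexp background and narrow log ratios. Counts with array weights in comparisons that use this group therefore leaned on those arrays. Whether this raised the counts was not tested. Slide as a fixed block gave 1068 for sex, where 1 slide held both sexes of wildtype mice.

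Diet by genotype in females (0) gave 2 genes with processed signals, no background subtraction and the median background, 1 with scale, 25 with slide as a fixed block and 3 in the value table. Diet by sex in knockouts (1) gave 11 with processed signals and the median background, 12 without background subtraction, 2 with all probes, 4 and 3 with slide as a fixed and random block, 0 with the replicate block and only the groups compared, 5 with array weights, 10 in the value table and 3 with the 8 arrays left out. With processed signals, no background subtraction, scale, the value table and the median background Gdpd3 was not among these genes. In wildtype mice (0) it gave 1 without background subtraction, with scale, slide as a random block, the value table and the median background. Genotype by sex (31) gave 87 with processed signals, 91 without background subtraction, 8 with scale, 77 and 54 with slide as a fixed and random block, 142 with array weights, 78 in the value table, 92 with the median background and 65 with the 8 arrays left out.

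Arrays with the same number were not taken as pairs, since in no comparison did all 6 such pairs correlate over 0.1. In wildtype females and males all 6 were positive (lowest 0.00460 and 0.0463, mean 0.269 and 0.232, 4 and 5 over 0.1) and lay on 1 slide each, against means of -0.0544 and -0.0460 for other numbers, and 4 and 3 correlated best with their own number. The replicate block moved the count of genes from 1360 to 1410 and 1986 to 2028 for genotype in females and males, 2711 to 2768 for sex, 31 to 34 for genotype by sex and 1 to 0 for diet by sex in knockouts, and no other count.

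With 1 array left out the counts were 1 to 2 and 0 to 1 for the diet in wildtype females and males, 1 to 5 and 2 to 6 in knockouts, 1017 to 1376 and 1572 to 2182 for genotype, and 2312 to 2782 for sex. They were 0 to 7 and 0 for diet by genotype in females and males, 0 to 7 and 0 to 1 for diet by sex in knockouts and wildtype mice, and 16 (without knockout female control 6) to 49 (without wildtype male control 3) for genotype by sex.

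Of the 336 list pairs, 107 passed, 89 to 125 under the other fits and 5 with an estimated correlation. The cell cycle list in knockout females on beta-carotene turned upward with processed signals (0.0857), no background subtraction (0.176), scale (4.43e-05), array weights (0.391), the value table (0.491) and the median background (0.108). Scale turned 18 other pairs. For the diet these were male-biased genes in wildtype (0.365) and knockout females (0.193), and in knockout males fatty acid oxidation (7.45e-06), extracellular matrix (0.348), female-biased (1.26e-05), male-biased (0.00103) and stellate cell lists (0.196). For genotype they were male-biased genes in females (0.000504), and in males fatty acid oxidation (0.992), xenobiotic (0.992) and female-biased lists (0.711). Among interactions they were male-biased genes (0.0874) for diet by genotype in females. In males they were fatty acid oxidation (0.410), xenobiotic (0.547), female-biased (0.0193) and male-biased lists (0.0201). They were also the cell cycle list for diet by sex in knockouts (0.124) and the xenobiotic list for genotype by sex (0.980). Without the 8 arrays fatty acid synthesis in wildtype males on beta-carotene (0.423) and NRF2 in knockout females (0.981) turned.

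No wildtype female array was among the 8, so leaving those out could not change the log2 fold changes of the diet in wildtype females. The 6 of 6 for that comparison is therefore hardly a test. Without the 8 arrays 6 of 6, 1 of 5, 8 of 13 and 8 of 9 lists kept call and direction for the diet in wildtype females and males and knockout females and males, 3 of 4 and 12 of 13 for genotype in females and males, and 14 of 14 for sex. For the interactions 6 of 9 and 10 of 11 kept them for diet by genotype, 8 of 10 and 1 of 5 for diet by sex in knockouts and wildtype mice, and 6 of 8 for genotype by sex. With the median background 4 of 6, 5 of 5, 11 of 13, 6 of 9, 2 of 4, 13 of 13, 13 of 14, 9 of 9, 9 of 11, 9 of 10, 3 of 5 and 8 of 8 kept them, in the same order. With slide as a fixed block 6 of 6, 4 of 5, 12 of 13, 9 of 9, 4 of 4, 12 of 13, 12 of 14, 9 of 9, 11 of 11, 10 of 10, 3 of 5 and 7 of 8 did. With processed signals 4 of 6, 5 of 5, 9 of 13, 7 of 9, 2 of 4, 12 of 13, 13 of 14, 9 of 9, 9 of 11, 9 of 10, 3 of 5 and 8 of 8 did, and with scale 0 of 6, 3 of 5, 8 of 13, 3 of 9, 2 of 4, 7 of 13, 11 of 14, 4 of 9, 2 of 11, 5 of 10, 2 of 5 and 3 of 8.

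Among tests of named genes under the alternatives other than Aquantile, 3618 kept their side of the threshold, 123 lost the call and 33 gained it. Where the main or the alternative fit called the gene, 0 changed direction. Direction was not compared where neither fit called it. The p of the locus test stayed above 0.05 with windows of 10 Mb (0.262 in females, 0.408 in males) and 40 Mb (0.723 and 0.0988). Genes below the background filter were not tested, and fold changes against dim groups are limits.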

Other observations

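With the median background, and chosen after their values were seen, Pttg1 on chromosome 11 and 5430405N12Rik on chromosome 14 split the same knockout arrays (correlation 0.96). Pttg1 ranged from -1.70 to 0.34 in knockout females on beta-carotene and from -1.64 to 0.46 in knockout female controls. In knockout males it ranged from -1.77 to 0.14 on the control diet and from 0.16 to 1.00 on beta-carotene. Wildtype female controls lay at 0.13 to 0.33. Trim12a lay at -3.40 to -3.00 in all 6 knockout males on beta-carotene and at 0.31 to 1.56 in knockout females on beta-carotene. Wildtype mice lay at -0.33 to 0.82. Its range was -3.43 to 1.06 in knockout female controls and -3.25 to 0.34 in knockout male controls. Gdpd3, also on chromosome 7 and also chosen after its values were seen, followed Trim12a inversely among knockout arrays. Where Trim12a lay at -3.43 to -2.85, Gdpd3 lay at 0.40 to 1.93. Where Trim12a lay at -0.14 to 1.56, Gdpd3 lay at -2.87 to 0.46. The level of Trim12a was spread unevenly over the diets, so for Gdpd3 the diet cannot be told apart from it.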
